A study of Rattus norvegicus with 12 samples.

How the data were processed

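Renal cortex RNA of 12 male Sprague-Dawley rats was measured, in 4 groups of 3: corn oil or BDCM (200 mg/kg per day for 4 weeks) in the CO2-O2 experiment (B92) and in the isoflurane experiment (B103). The scanner files hold intensity values that the authors made with Agilent Feature Extraction 10.7 (per the submitters' processing notes; 10.7.1.1 per the file headers), with background subtraction and detrending within each array and no scaling between arrays. The deposited value table holds a linear ratio, each array's processed signal divided by its 75th percentile, with column medians of 0.1001 to 0.1120, so it is not centred. RNA preparation and labelling details beyond this are not given in the sources used here.

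Each of the 6 isoflurane columns of the value table equals the scaled signal of its own scanner file. Each of the 6 CO2-O2 columns equals that of another animal of the same group (22245 probes compared). Animals are numbered here by their scanner files, and group membership is the same either way. The value table was used for this comparison, as an alternative to the scanner signal and for the animal numbers of an alternative block.

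The array carries 62976 spots, 61657 non-control probes and 1319 controls, and 84 spike-in (ERCC) probes were left out of the tests. Probe annotation refers to genome build rn4, and no coordinates were used. RefSeq accessions were turned into gene symbols with a RefSeq gene table of assembly GRCr8: of 33356 probes with an accession, 27460 matched 1 symbol, 0 matched several, and 34197 probes had none here (15284 symbols). Where a gene had several probes (8807 symbols), the probe with the highest mean signal stood for it.

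Processed signals were divided by each array's 75th percentile and put on the log2 scale. Spots marked as outliers by Feature Extraction were removed (54 missing values). Features had to be well above background on all 3 arrays of at least 1 group, which kept 34218 of 49397 features (12208 named genes, 22010 without a symbol). Features were fitted with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8) with 1 mean per group, and adjusted p is Benjamini and Hochberg's over all features. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The contrasts were BDCM minus oil in each experiment, their mean, their difference, and isoflurane minus CO2-O2 in controls and in BDCM groups. The threshold was an adjusted p of 0.05.

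Where a gene was not well above background in 1 of the groups compared, a fold is given as a lower bound, with each of that group's signals raised to at least the lowest signal that was well above background on the same array. Where a group had 1 or 2 arrays with the gene well above background, the measured difference is given with their number, and the difference with signals raised in the same way beside it. Gene lists (35, with at least 5 members tested) were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Ranges given for lists leave out the estimated correlation, whose value is given apart. The number of members, and members passing when adjusted over the list alone, are given beside each.

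Samples, groups, contrasts, gene lists, the first set of alternatives and the rule for naming genes were chosen before the data were examined. That rule names the 12 highest and 12 lowest mean effects among genes called in both experiments with the same sign and no overlap between groups, 4 per direction in each experiment, up to 6 per direction for the difference, 10 for controls and 5 for BDCM groups, up to 4 passing members of each list, and 10 fixed genes (Havcr1, Cdkn1a, Hmox1, Nqo1, Cyp2e1, Gstt1, Fos, Egr1, Hspa1a and 1 more). It gave 210 genes, some of which are not reported here. Gene families, hepatocyte lists and the blocks by scan day, array row and value table number were chosen after the data were seen, as was leaving out both isoflurane animals with high liver transcripts.

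Alternatives changed the scaling (quantile, median), background correction (normexp with an offset of 50), filter, probe choice, model (array weights, trend, slide as a fixed or random block, groups compared alone), threshold (0.01, or 2-fold) and list test, and left out each animal in turn. For normexp, median spot signals were used, in place of mean spot signals, which the files used here do not hold. Slides and scan days follow the experiments: 4 of the 6 CO2-O2 arrays lay on slide 1, and no slide or scan day held arrays of both experiments. With slide as a fixed block the CO2-O2 effect therefore rests on 1 treated animal and the isoflurane effect on 1 control.

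The steps were tested on simulated data (34164 features). For the CO2-O2 BDCM effect 29.9, 64.2 and 89.4% of features changed 1.5, 2 and 4-fold were recovered, for the isoflurane effect 41.8, 70.2 and 90.9%, for the mean 61.2, 82.1 and 95.5%, and for the difference of effects 14.9, 43.3 and 77.3%. In that order, 5 of 127, 15 of 280, 16 of 278 and 4 of 94 calls were false. Each comparison was scored on 200 changed features, far fewer than the data call, so these values belong to a sparser setting. In a simulation of the lists for the mean effect, the 1 shifted list was called and 0 of the others. This does not tell how correlation between genes affects the list calls in the data. The number of arrays, 3 per group, limits the precision.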

Results

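Gene expression was measured in the renal cortex of 12 male Sprague-Dawley rats on 1-colour Agilent arrays, with 1 array per animal. Bromodichloromethane (BDCM), a by-product of water chlorination that injures rodent kidney and liver, was given for 4 weeks at 200 mg/kg per day, and control rats received the corn oil vehicle. Tissue was taken 24 h after the last dose. Animals were killed under CO2-O2 anaesthesia in one experiment and under isoflurane in the other, which gave 4 groups of 3 animals. Between 41529 and 44714 of the 61657 non-control probes (67.4 to 72.5%) were well above background on each array. The 75th percentile of the processed signal ran from 1079.5 to 1476.5 intensity units, and 0 to 6 probes per array were saturated. The number of arrays, 3 per group, limits the precision. In all, 34218 features were tested, 12208 of them genes named through their RefSeq transcript.

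The first question was which transcripts the renal cortex changed under BDCM, averaged over both experiments (6 treated and 6 control animals). The kidney injury marker Havcr1 (KIM-1), which injured proximal tubule cells place on their surface, rose 25.7-fold (95% confidence interval 11.8 to 56.0; adjusted p = 6.92e-05). Osteopontin (Spp1) rose 9.73-fold and the glycoprotein gene Gpnmb rose 25.2-fold. Single genes of amino acid supply and stress rose strongly too. Asparagine synthetase (Asns) rose by 4.01 ± 0.14 on the log2 scale (SE, n = 6 per treatment; adjusted p = 2.52e-07), the proline synthesis enzyme Pycr1 rose 81.9-fold, and the pseudokinase Trib3 rose 21.7-fold. The male-specific cytochrome P450 Cyp2c11 fell by 4.68 ± 0.55 (adjusted p = 1.31e-04). In each of these genes all 3 treated animals lay beyond all 3 controls in both experiments.

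**Figure D1:**
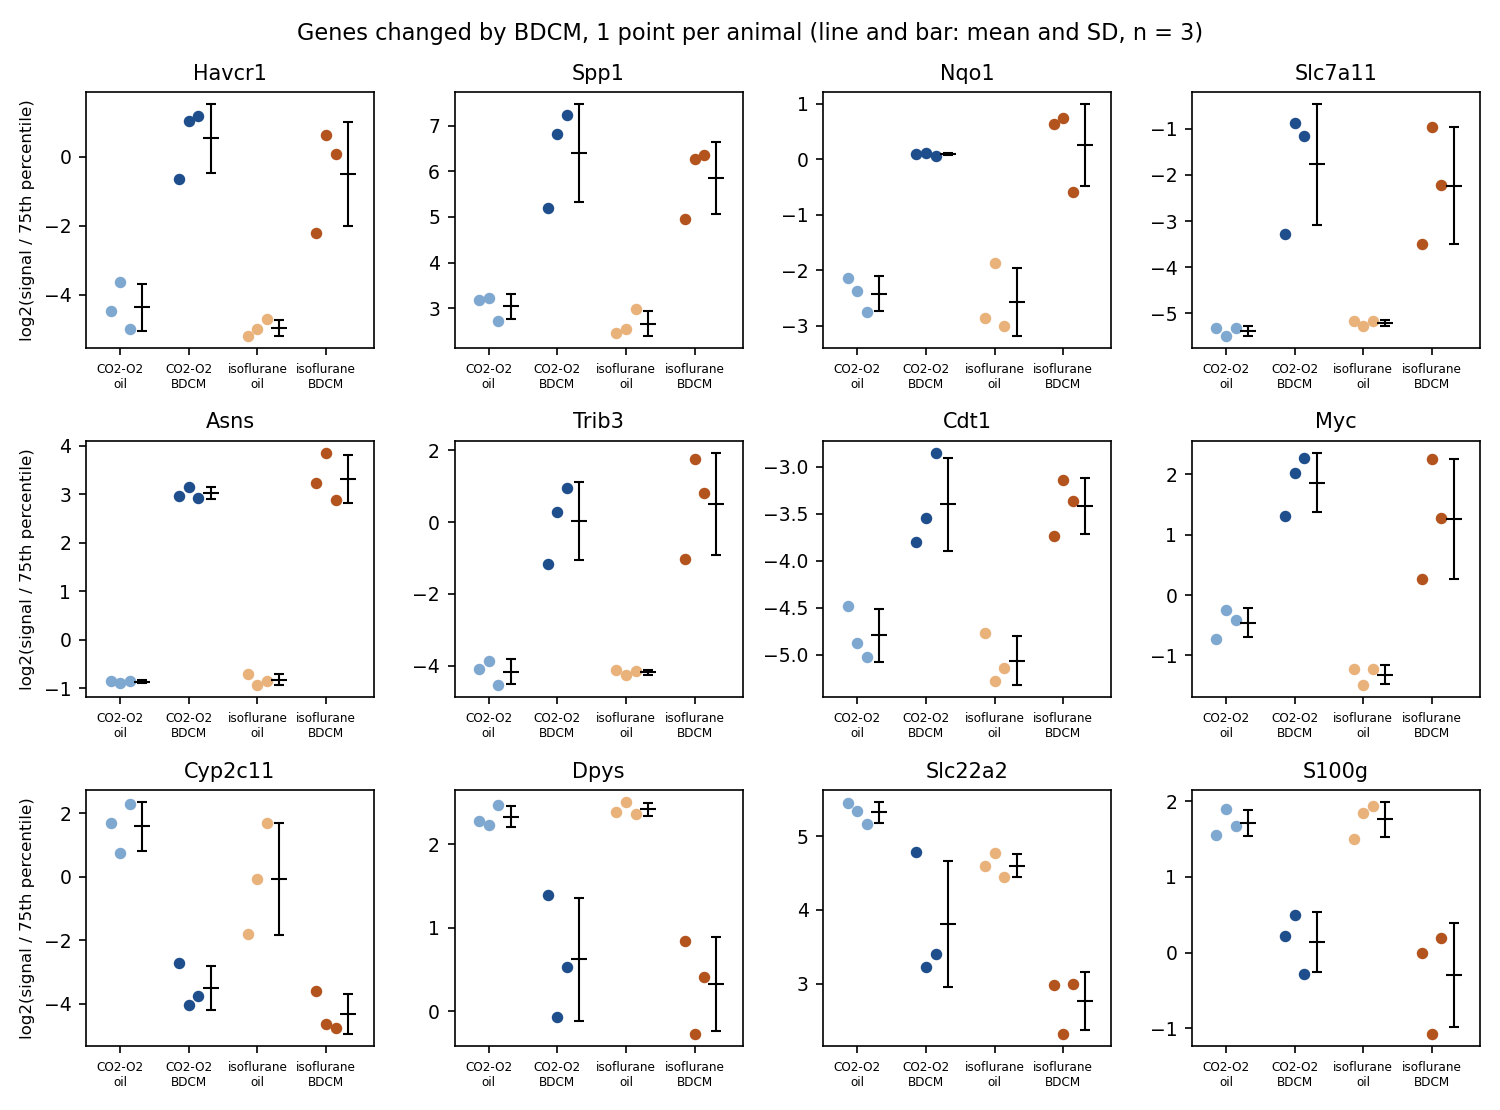
Normalized log2 signal of 12 genes in each of the 12 animals, with each group's mean and SD (n = 3). Havcr1, Spp1, Nqo1, Slc7a11, Asns, Trib3, Cdt1 and Myc were higher and Cyp2c11, Dpys, Slc22a2 and S100g were lower in BDCM-treated animals of both experiments, with Havcr1 up 25.7-fold on average.

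Other genes with large rises came from several processes. Cox6a2, the muscle form of a cytochrome c oxidase subunit, rose 109-fold (adjusted p = 2.73e-06). The drug efflux pump Abcc2 rose 23.2-fold, the glucuronosyltransferase Ugt2b7 27.6-fold, and Stra6l, a receptor for retinol-binding protein, 22.6-fold. For the fucosyltransferase Fut1 the rise was at least 23.7-fold and at least 21.8-fold in the CO2-O2 and isoflurane experiments, and for the cholesterol transporter Npc1l1 at least 6.24-fold and at least 6.78-fold. Hrk, a BH3-only gene of the apoptosis machinery, rose at least 29.5-fold in the CO2-O2 experiment and by 5.01 on the log2 scale in the isoflurane experiment (at least 28.3-fold with signals raised to the background limit, as 1 of 3 controls was well above background). All of these separated treated from control animals without overlap in both experiments.

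Among the genes that fell most were Hrg (histidine-rich glycoprotein, by 3.10 ± 0.46 on the log2 scale; adjusted p = 5.70e-04), Cilp (a matrix protein of cartilage, by 2.76 ± 0.38) and Guca2b (uroguanylin, a peptide that promotes salt excretion, by 2.66 ± 0.16, adjusted p = 1.93e-06). Cndp1, a carnosine-cleaving dipeptidase, fell by 2.56 ± 0.30, the annexin gene Anxa13 by 2.40 ± 0.34, Iqch by 2.76 ± 0.46, the kinase gene Mylk3 by 2.57 ± 0.32 and Tm4sf20 by 2.51 ± 0.42. Dnajc5b was at least 5.98-fold lower in treated animals of the CO2-O2 experiment and at least 3.10-fold lower in the isoflurane experiment, and the cold-sensing channel Trpm8 at least 2.88-fold and at least 2.97-fold lower. The major urinary protein gene Mup4l1 fell by 3.95 on the log2 scale with CO2-O2, and was at least 1.40-fold lower with isoflurane (adjusted p = 0.0372; 0.0210 to 0.339 over the alternatives, past the threshold in 14 of 27). The isoflurane call of Mup4l1 ended, among others, with slide (0.0963) or scan day (0.0936) as a block and without isoflurane control 2 (0.0788) or 3 (0.124) or isoflurane treated animal 2 (0.116) or 3 (0.104), and that of Trpm8 with slide (0.236) or scan day (0.0661) as a block and without isoflurane control 1 (0.0575) or 3 (0.0616) or isoflurane treated animal 2 (0.0884) or 3 (0.0534; range 0.00253 to 0.236). Major urinary proteins are made mainly in liver, and liver transcripts differed widely between the animals: albumin (Alb) signal lay between -1.44 and 1.66 on the normalized log2 scale in the 6 animals of the CO2-O2 experiment and between -8.07 and -0.69 in the 6 of the isoflurane experiment.

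Among Nrf2 targets and among stress response genes more rose than fell. Of 29 measured Nrf2 target genes 16 rose, 5 fell and 8 did not pass the test (16 and 5 when adjusted over the list alone). The aldo-keto reductase Akr1b8 rose 12.5-fold, the cystine transporter Slc7a11 9.74-fold and the quinone reductase Nqo1 6.39-fold (2.67 ± 0.26, adjusted p = 3.48e-05). The list stood above other genes (camera, adjusted p = 1.93e-04, median 0.38), though not with an estimated correlation between genes (adjusted p = 0.544 with an estimated correlation). Hmox1, another Nrf2 target, differed by 0.44 ± 0.42 (adjusted p = 0.435; 0.00711 without isoflurane control 2, range 0.00711 to 0.752 over the alternatives). Of 33 endoplasmic reticulum stress and amino acid response genes 24 rose, 3 fell and 6 did not pass (24 and 4 when adjusted over the list alone; camera, adjusted p = 8.04e-07, median 0.61, adjusted p = 0.544 with an estimated correlation). Besides Asns and Trib3, the stress-induced transcription cofactor Nupr1 rose 19.2-fold (4.26 ± 0.31) and Derl3, a component of endoplasmic reticulum-associated degradation, 16.3-fold (4.02 ± 0.53).

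Glutathione enzymes moved apart. Of 32 measured glutathione conjugation and breakdown genes 7 rose, 13 fell and 12 did not pass the test, with the same counts when adjusted over the list alone, and the list as a whole did not differ from other genes (camera, adjusted p = 0.612, median -0.13, mean 0.05). The transferases Gstm1, Gstp1 and Gstm5 rose 15.6-fold, 5.15-fold and 5.02-fold, while Kyat1, a cysteine conjugate beta-lyase, fell by 1.46 ± 0.16 (adjusted p = 9.02e-05). Gstt1, the theta-class transferase that conjugates small halomethanes, fell by 0.59 ± 0.15 (adjusted p = 0.0107). Of 36 cytochrome P450 and conjugation enzymes 4 rose, 18 fell and 14 did not pass (4 and 19 when adjusted over the list alone; camera, adjusted p = 0.0133, median -0.38, adjusted p = 0.544 with an estimated correlation). The sulfotransferase Sult1c2 fell by 2.39 ± 0.39 and the epoxide hydrolase Ephx1 rose 3.44-fold. Cyp2e1, the P450 that oxidises halomethanes, fell by 0.67 ± 0.22 (adjusted p = 0.0335), a call that 11 of 27 alternatives ended (0.268 with slide as a fixed block, the highest of the range from 0.0105). Among them were leaving out CO2-O2 control 1 (0.0527) or 2 (0.0740), CO2-O2 treated animal 3 (0.0660), isoflurane control 1 (0.0641) or 3 (0.0722) and isoflurane treated animal 2 (0.0702) or 3 (0.0576). Cyp2c11 and other P450 genes are also abundant in liver, whose transcripts varied between animals as given for albumin.

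Cell cycle genes passed as a list in both experiments, and kidney injury markers with CO2-O2 and not with isoflurane. The cell cycle call was kept in 28 of 29 alternatives in each experiment (highest adjusted p over the alternatives 0.079 with CO2-O2 and 0.0501 with isoflurane). An estimated correlation ended every list call of both experiments. Of 27 kidney injury markers 13 rose, 4 fell and 10 did not pass the test (13 and 4 when adjusted over the list alone), led by Havcr1, Gpnmb, Spp1 and the fibrinogen chain Fgb, which rose 5.42-fold (2.44 ± 0.43, adjusted p = 0.00163). Their camera call (adjusted p = 0.0287, median 0.32, adjusted p = 0.544 with an estimated correlation) ended under quantile normalization (0.0607), with every probe as its own feature (0.193), with slide (0.0779) or scan day (0.0592) as a block and without isoflurane BDCM animal 3 (0.0634). The range over these and the other alternatives was 0.00466 to 0.193. On its own the list passed with CO2-O2 (adjusted p = 0.00520, 10 rose and 0 fell), a call that an estimated correlation ended (0.735), and not with isoflurane (adjusted p = 0.185, 7 rose and 3 fell). The adjusted p for the difference was 0.0411 (0.820 with an estimated correlation and 0.955 by fry). Of 38 cell cycle genes 24 rose, 1 fell and 13 did not pass (30 and 1 when adjusted over the list alone; camera, adjusted p = 1.42e-07, median 0.82, adjusted p = 0.544 with an estimated correlation). The replication licensing genes Cdt1 and Cdc6 rose by 1.52 ± 0.18 and 1.52 ± 0.23, cyclin E1 (Ccne1) by 1.45 ± 0.29 and Gins2 by 1.22 ± 0.16, where Cdc6 and Gins2 were well above background in 1 of 3 isoflurane controls. Of 21 p53 target genes 8 rose, 4 fell and 9 did not pass (12 and 4 when adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.0536, adjusted p = 0.544 with an estimated correlation, 0.00392 to 0.196 over the other alternatives).

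Within the p53 list Gdf15 rose by 1.99 ± 0.26, the death receptor gene Fas by 1.54 ± 0.22 and Bbc3 (PUMA) by 1.30 ± 0.15, and Plk3 fell by 1.20 ± 0.15 (adjusted p = 1.76e-04). The cell cycle inhibitor Cdkn1a differed by -0.02 ± 0.10 on the probe used (adjusted p = 0.900), but its other 2 probes rose by 1.57 ± 0.38 and 2.53 ± 0.47, and the mean of its probes rose by 1.36 (adjusted p = 0.00264, the lowest of a range up to 0.997). Of 28 immediate early genes 11 rose, 7 fell and 10 did not pass the test, also when adjusted over the list alone (camera, adjusted p = 0.139, median 0.18). Myc rose 5.49-fold (2.46 ± 0.30, adjusted p = 1.55e-04), Atf3 rose 6.69-fold, and Fosl1 rose at least 10.8-fold in the CO2-O2 experiment. Fos differed by 0.34 ± 0.17 (adjusted p = 0.149; 0.0113 to 0.492 over the alternatives, past the threshold with slide as a fixed block and with the mean of probes) and Egr1 by 0.21 ± 0.23 (adjusted p = 0.507; 0.0192 without CO2-O2 control 2, the lowest of a range up to 0.815).

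Most proximal tubule markers fell. Of 45 proximal tubule markers 33 fell, 3 rose and 9 did not pass the test, with the same counts when adjusted over the list alone (camera, adjusted p = 4.16e-07, median -0.63, adjusted p = 0.544 with an estimated correlation). Dihydropyrimidinase (Dpys) fell by 1.90 ± 0.24 (adjusted p = 2.32e-04), the amino acid transporter Slc7a13 by 1.81 ± 0.36, the organic anion transporter Slco1a1 by 1.81 ± 0.30 and the organic cation transporter Slc22a2 by 1.67 ± 0.25. Of 40 fatty acid oxidation genes and PPAR alpha targets 20 fell, 5 rose and 15 did not pass (22 and 5 when adjusted over the list alone; camera, adjusted p = 0.00799, median -0.31, adjusted p = 0.567 with an estimated correlation). The peroxisomal gene Pex11a fell by 1.01 ± 0.17, while the lipid droplet gene Cidea rose by 1.73 ± 0.22. Ehhadh fell by 1.18 ± 0.30 (adjusted p = 0.0111; 0.00298 to 0.117 over the alternatives, 0.117 with slide and 0.0507 with scan day as a fixed block). Of 36 mitochondrial respiratory chain genes 20 fell, 1 rose and 15 did not pass (24 and 1 when adjusted over the list alone; camera, adjusted p = 1.93e-04, median -0.17, adjusted p = 0.544 with an estimated correlation). Atp5f1b fell by 0.52 ± 0.07 and Sdha by 0.45 ± 0.08.

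Among endocrine and mineral genes more fell than rose. Of 18 phosphate, calcium and vitamin D genes 13 fell, 3 rose and 2 did not pass (14 and 3 when adjusted over the list alone; camera, adjusted p = 0.00697, median -0.42, adjusted p = 0.544 with an estimated correlation). The calcium-binding protein S100g fell by 1.81 ± 0.22 (adjusted p = 1.61e-04), Cyp27b1, which activates vitamin D, by 1.17 ± 0.20 and the parathyroid hormone receptor Pth1r by 1.09 ± 0.11. Of 23 growth hormone, androgen and male-biased genes 13 fell, 2 rose and 8 did not pass, also when adjusted over the list alone (camera, adjusted p = 0.00697, median -0.64, adjusted p = 0.544 with an estimated correlation). The prolactin receptor Prlr fell by 1.65 ± 0.33 and Igfbp1 rose by 1.74 ± 0.24. Liver expresses several of these genes, and liver transcripts differed between animals as given for albumin. Of 20 angiotensin system and vasoactive genes 8 fell, 0 rose and 12 did not pass, also when adjusted over the list alone (camera, adjusted p = 0.0323, median -0.36, adjusted p = 0.544 with an estimated correlation). Angiotensinogen (Agt) fell by 1.35 ± 0.25. That list's call ended with slide (0.110) or scan day (0.0820) as a fixed block, with slide as a random block (0.0825), and without CO2-O2 control 2 (0.0553) or isoflurane BDCM animal 2 (0.0631). The range over these and the other alternatives was 0.00604 to 0.110.

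Where they changed, most cholesterol genes rose and most glucocorticoid-induced genes fell. Of 25 cholesterol synthesis and uptake genes 12 rose, 2 fell and 11 did not pass (13 and 2 when adjusted over the list alone; camera, adjusted p = 0.00707, median 0.18, adjusted p = 0.544 with an estimated correlation). The squalene epoxidase gene Sqle rose by 0.71 ± 0.10 (adjusted p = 5.52e-04) and Insig1, a sterol sensor, by 0.64 ± 0.07 (adjusted p = 5.85e-05). Of 21 glucocorticoid-induced genes 9 fell, 1 rose and 11 did not pass (9 and 2 when adjusted over the list alone; camera, adjusted p = 0.0320, median -0.44, adjusted p = 0.544 with an estimated correlation). The metallothionein Mt1 fell by 1.40 ± 0.21, Pck1 by 1.31 ± 0.25 and the clock gene Per1 by 1.27 ± 0.20. Their camera call ended with the mean of probes (0.0546), without both isoflurane animals with high liver transcripts (0.0769) and without CO2-O2 control 2 (0.0553) or isoflurane BDCM animal 1 (0.0621). The range over these and the other alternatives was 0.00392 to 0.0769.

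Markers of other kidney cells fell more often than they rose. Of 13 distal convoluted and connecting tubule markers 8 fell, 0 rose and 5 did not pass (9 and 1 when adjusted over the list alone; camera, adjusted p = 0.0112, median -0.27, adjusted p = 0.546 with an estimated correlation), among them the sodium-calcium exchanger Slc8a1 (-0.75 ± 0.10) and Klotho (Kl, -0.59 ± 0.10). Of 21 podocyte and glomerular markers 14 fell, 1 rose and 6 did not pass (15 and 1 when adjusted over the list alone; camera, adjusted p = 0.00281, median -0.39, adjusted p = 0.544 with an estimated correlation), among them Plce1 (-0.62 ± 0.08) and Wt1 (-0.59 ± 0.10), while Cd2ap rose by 0.89 ± 0.14. Of 17 stromal and smooth muscle markers 8 fell, 0 rose and 9 did not pass (10 and 0 when adjusted over the list alone; camera, adjusted p = 0.0112, median -0.34, adjusted p = 0.544 with an estimated correlation), with Gpx3 at -0.72 ± 0.12 and Rgs5 at -0.47 ± 0.10. Of 27 extracellular matrix genes 14 fell, 2 rose and 11 did not pass (15 and 2 when adjusted over the list alone; camera, adjusted p = 0.0112, median -0.41, adjusted p = 0.567 with an estimated correlation). Ccn2 fell by 1.22 ± 0.29 (adjusted p = 0.00748; 0.0614 and 0.0524 with slide and scan day as blocks, range 0.00164 to 0.0614). Of 20 endothelial markers 6 fell, 0 rose and 14 did not pass, also when adjusted over the list alone, with Tie1 at -0.60 ± 0.09. Their call (camera, adjusted p = 0.0323, median -0.21, adjusted p = 0.586 with an estimated correlation) ended with the mean of probes (0.0546), slide as a random block (0.0879), scan day as a block (0.0524) and without isoflurane BDCM animal 2 (0.0906). The range over these and the other alternatives was 0.00571 to 0.0906.

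The remaining lists did not pass as groups, with camera adjusted p from 0.111 to 0.785. Of 15 thick ascending limb markers 4 fell (Ptger3 by 0.66 ± 0.09) and of 18 collecting duct principal cell markers 6 fell and 2 rose (Krt7 fell by 1.16 ± 0.11, Cldn4 rose by 0.94 ± 0.16). Of 17 intercalated cell markers 8 fell and 2 rose, with the anion exchanger pendrin (Slc26a4) at -1.06 ± 0.14. Hypoxia-induced genes went both ways, 5 up and 5 down of 25 (Ankrd37 fell by 1.46 ± 0.12, Bnip3 rose by 0.74 ± 0.10). Of 39 interferon-induced genes 8 rose and 5 fell, with Ifi27l2b up 6.99-fold and Cd74 down by 1.05 ± 0.18. Of 25 inflammatory cytokine and adhesion genes 6 rose and 2 fell, with the TWEAK receptor Tnfrsf12a up 4.66-fold and Birc3 up by 0.97 ± 0.18. Of 18 heat shock genes 2 rose over all genes and 0 when adjusted over the list alone (the inducible Hsp70 gene Hspa1a differed by 0.41 ± 0.27, adjusted p = 0.250; 0.0451 without CO2-O2 treated animal 2, the lowest of a range up to 0.975). Among circadian clock genes 2 of 18 rose and 4 fell. Of 24 macrophage and monocyte markers 2 rose and 4 fell, of 24 lymphocyte markers 1 fell, of 9 neutrophil markers 1 fell (Padi4, by 1.61 ± 0.34, adjusted p = 0.0586 with slide as a fixed block in a range from 1.13e-05), of 11 red blood cell markers 5 fell and 1 rose, of 13 adipocyte markers 2 fell and 1 rose, and of 7 adrenal markers 2 fell (Npy by 0.91 ± 0.13). For neutrophil markers the median (0.02) and the mean (-0.27) differed in sign.

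**Figure D2:**
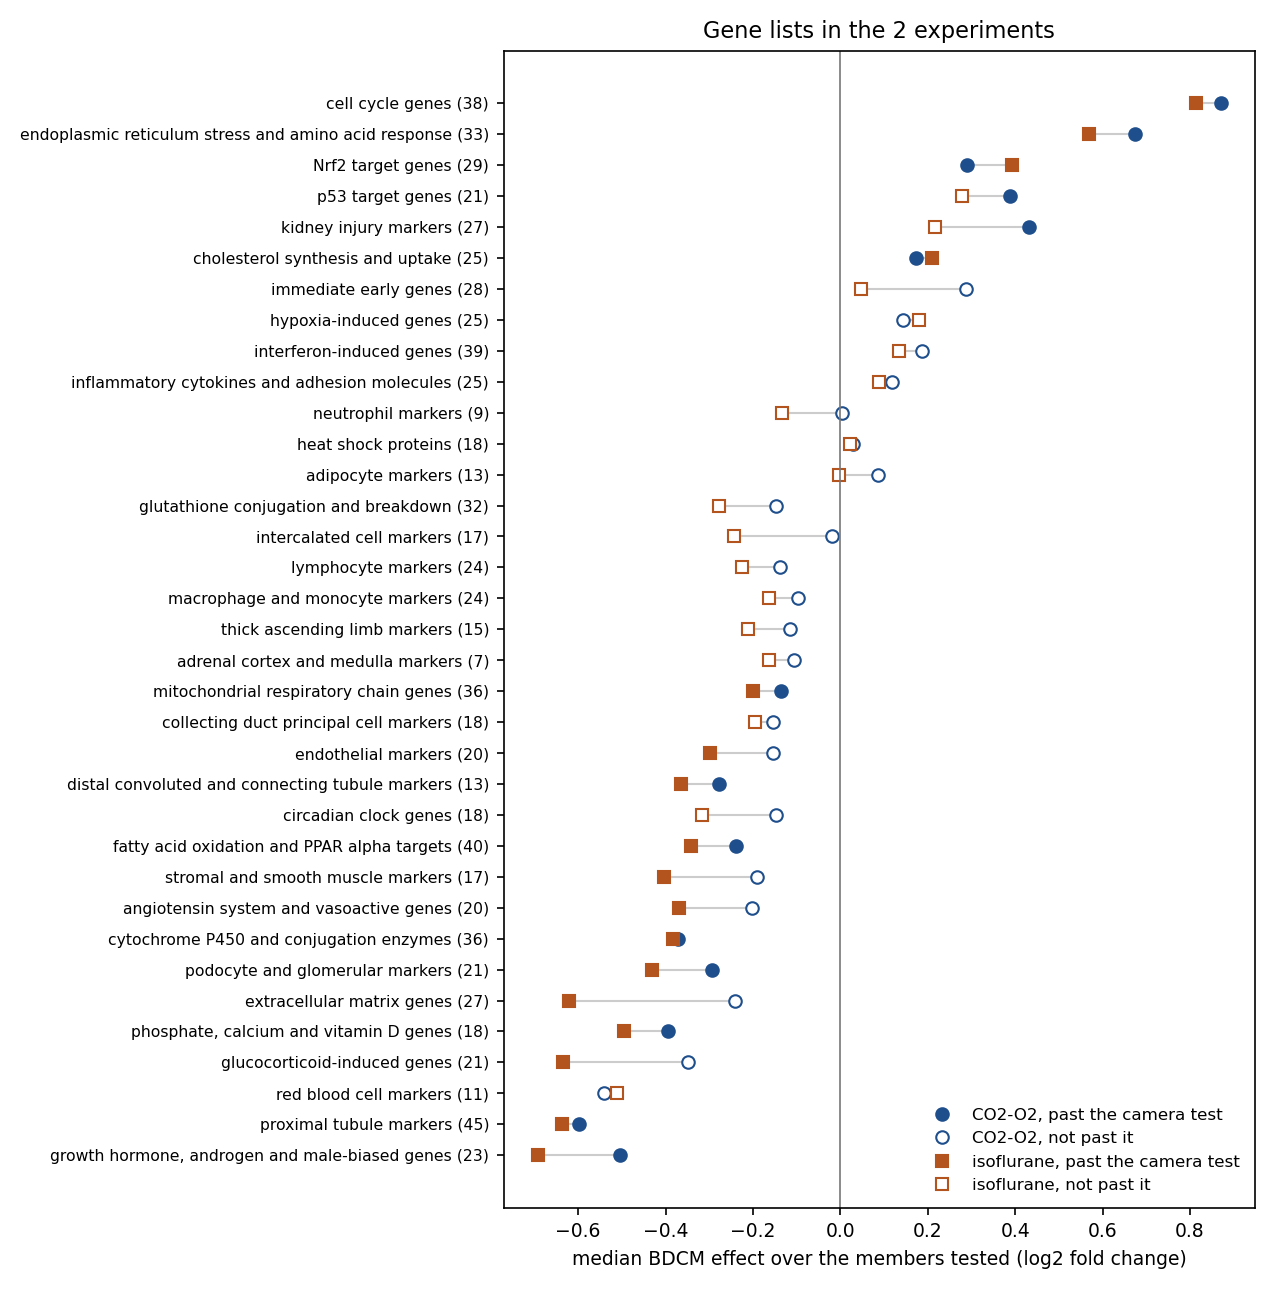
Median log2 BDCM effect of each of the 35 gene lists, with the number of members tested in brackets, in the CO2-O2 experiment (circles) and the isoflurane experiment (squares). Filled symbols passed camera at an adjusted p under 0.05, and the cell cycle list (median 0.82 over both experiments) and the proximal tubule list (-0.63) lie far from 0 on opposite sides.

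By limma, the mean BDCM effect passed an adjusted p of 0.05 in 13037 of 34218 features, 6071 higher and 6966 lower, of which 1821 changed at least 2-fold. Among named genes 2358 rose and 2545 fell. With slide as a fixed block the count was 8329, of which 7403 were also among the 13037. Of the 35 lists, 18 passed camera (5 up, 13 down), 22 passed fry and 0 passed camera with an estimated correlation between genes.

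In the CO2-O2 experiment on its own, large rises were those of Cox6a2 (97.1-fold), Pycr1 (6.18 on the log2 scale) and Hrk (at least 29.5-fold). Large falls were those of Cyp2c11 (34.1-fold, adjusted p = 0.00165), Mup4l1 (15.4-fold, adjusted p = 0.00471, or 14.8-fold with signals raised, as 2 of 3 treated animals were well above background), Mup4l4 (11.6-fold, adjusted p = 0.00585), Mup4 (at least 6.08-fold lower; adjusted p = 0.00198) and Dnajc5b. Havcr1 went from -4.36 ± 0.68 in controls to 0.53 ± 1.01 in treated animals on the normalized log2 scale (SD, n = 3 each). Groups did not overlap in any of these genes. Major urinary protein genes fell here while the liver genes Alb (0.76 ± 1.63), Ttr (0.89 ± 1.68) and Mug1 (0.13 ± 1.36) did not pass the test (adjusted p = 0.786, 0.753 and 0.957). By limma 6810 features passed, 3426 higher and 3384 lower (1160 and 1228 among named genes), and 13467 features (39.4%) did not overlap between groups, against the 10% that chance gives. The count was 3167 with slide as a fixed block and also within slide 1, the only slide with both groups (3 controls and 1 treated animal), and 4104 with scan day as a block. It was 4386 without control 2, 3901 without control 3 and 4200 without treated animal 3.

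In the isoflurane experiment large rises were those of Cox6a2 (6.93 on the log2 scale), Pycr1 (6.53) and Fut1 (at least 21.8-fold). Large falls were those of Cyp2c11 (19.3-fold, adjusted p = 0.00337), Hrg (-3.65), apolipoprotein B (Apob, 10.6-fold, adjusted p = 1.14e-04) and Cilp (-3.27). The size of the Apob fall depended on the probe: with isoflurane its other probes differed by -3.82, -3.28, -1.21 and -0.82, the last not past the test (limma, adjusted p = 0.171). Apob, a secreted lipoprotein component, differed by -1.14 in the CO2-O2 experiment (adjusted p = 0.0543), and the difference between experiments did not pass. Havcr1 went from -4.97 ± 0.24 to -0.49 ± 1.52 (SD, n = 3 each). Groups did not overlap in any of these genes. By limma 8923 features passed, 4525 higher and 4398 lower (1648 and 1682 among named genes), and 14800 features (43.3%) did not overlap between groups (10% by chance). The count was 2715 with slide as a fixed block and within slide 4 (1 control and 2 treated animals), 7978 within scan day 3 (3 controls and 2 treated animals), and 5446 without treated animal 2.

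With slide as a fixed block some calls of single genes ended in 1 or both experiments, with the direction unchanged. That block leaves the CO2-O2 effect resting on treated animal 2 against the controls. It leaves the isoflurane effect resting on control 3 against treated animals 1 and 2. An ended call can therefore come from the loss of animals. In the CO2-O2 experiment scan day divides the arrays as slide does, so its values are no separate check. Ugt2b7 then had an adjusted p of 0.109 with CO2-O2 and 0.0945 with isoflurane (ranges over the alternatives 0.00194 to 0.109 and 0.00759 to 0.0945), Trib3 0.0524 and 0.0635 (5.39e-04 to 0.0524 and 1.63e-04 to 0.0635), Cndp1 0.0505 and 0.0870 (8.79e-04 to 0.0505 and 7.28e-04 to 0.0870), and Hrg 0.302 and 0.0714 (0.00908 to 0.302 and 9.89e-04 to 0.0714). With scan day as a block the CO2-O2 values were 0.0824 for Ugt2b7 and 0.259 for Hrg, and the CO2-O2 call of Hrg also ended without control 1 (0.0767), control 2 (0.0523) or treated animal 3 (0.0807). For Havcr1 the isoflurane value was 0.0946 (2.02e-04 to 0.0946). Of the 142 named-gene calls of the mean effect, 106 were kept with slide as a fixed block and 129 whichever animal was left out.

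Lists passed camera in 14 cases with CO2-O2 (6 up, 8 down) and 17 with isoflurane (4 up, 13 down). Nrf2 target genes (adjusted p = 4.26e-05 and 6.46e-04), cell cycle genes (2.61e-07 and 4.15e-06) and endoplasmic reticulum stress and amino acid response genes (1.14e-06 and 3.70e-06) stood higher in both, and proximal tubule markers lower in both (4.73e-06 and 1.43e-07; medians -0.60 and -0.64). With an estimated correlation these p-values were 0.735 with CO2-O2 and 0.557 with isoflurane. Glucocorticoid-induced genes and angiotensin system and vasoactive genes passed with isoflurane (0.0237 each) and not with CO2-O2 (0.0575 and 0.0932), and their difference did not pass (0.343 and 0.219). For CO2-O2 the number of lists was 8 with slide or scan day as a fixed block, 9 with slide as a random block, 9 by fry and 8 without treated animal 3. Within slide 1 all 14 lists kept their direction and 7 passed, and within slide 4 and within scan day 3 all 17 isoflurane lists kept theirs and passed. Slide 1 holds 1 treated animal and slide 4 holds 1 control, so those values rest on 1 animal in an arm. Their spread was taken from arrays that share both group and slide with another array, which leaves those single animals out.

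The next question was whether the BDCM effect differed between the experiments. Most features called in either experiment had the same sign in the other: of the 6810 features called with CO2-O2, 6689 (98.2%) had the same sign with isoflurane, and of the 8923 called with isoflurane, 8719 (97.7%) had the same sign with CO2-O2. In both experiments 2935 features rose (453 would by independent lists) and 2368 fell (435 by independent lists), and 7 were called in opposite directions, among them Psd2 (0.57 and -0.60) and the interferon-induced GTPase gene Ifi47 (0.50 and -0.58). The 2 effects correlated across all features with r = 0.766 (jackknife SE over animals 0.0362) and rho = 0.721, where features are not independent replicates and the experiments share no animals. The correlation was 0.708 for the effect within slide 1, 0.719 within slide 4 and 0.744 within scan day 3. The difference of effects passed limma's test in 0 features (1731 with an unadjusted p under 0.05, 1711 expected; smallest adjusted p = 0.537). It passed in 11 with slide and 20 with scan day as a fixed block, and in 1 feature each without CO2-O2 control 3, CO2-O2 treated animal 1 or isoflurane treated animal 2, the first of them Adtrp.

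**Figure D3:**
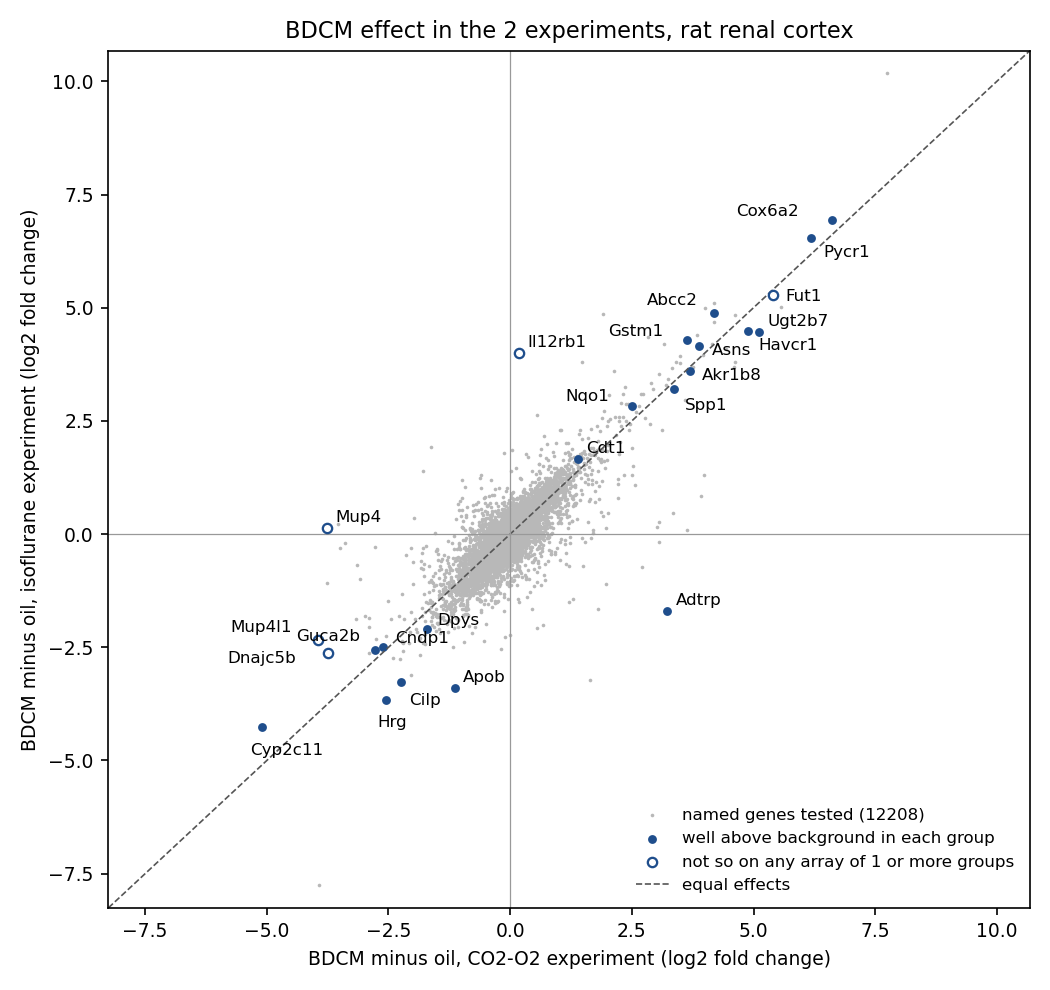
Log2 BDCM effect of each of the 12208 named genes in the CO2-O2 experiment (x axis) and in the isoflurane experiment (y axis), with the dashed line marking equal effects and open circles marking labelled genes not well above background in at least 1 group. Pycr1 (6.18 and 6.53) and Cyp2c11 (-5.09 and -4.27) lie near the line, and Mup4 (-3.77 and 0.14, not well above background in either isoflurane group) and Adtrp (3.22 and -1.70, neither past the test) lie far from it. The position of Adtrp belongs to the probe used. Its other probes differed by -0.825 and -0.692 with CO2-O2 and by -0.381 and -0.349 with isoflurane.

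Although no single gene passed, 8 lists were shifted lower with isoflurane than with CO2-O2 by camera, led by extracellular matrix genes (adjusted p = 1.59e-05; median difference -0.34) and stromal and smooth muscle markers (4.19e-04; -0.22). No member of any of these lists passed the test of the difference. With an estimated correlation the adjusted p was 0.820 for each of the 8, and by fry 0 lists passed. Their number ran from 2 without isoflurane control 3 to 15 without isoflurane treated animal 1, and was 4 without CO2-O2 control 1, 3 without isoflurane control 1 and 4 without isoflurane treated animal 2.

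Controls of the 2 experiments were compared to see what differed with the anaesthesia, which in this series also changes with the experiment, the slides and the scan days. Several transcripts abundant in liver were lower in the isoflurane controls. Transthyretin (Ttr) fell by 6.57 ± 1.68 on the log2 scale (SE, n = 3 per group; adjusted p = 0.0337), the odorant-binding protein Obp3 by 5.83 ± 1.30, the plasma proteinase inhibitors Mug1 by 5.28 ± 1.36 and Mug1l1 by 5.07 ± 1.16, and the urinary protein Rup2 by 5.63 ± 1.55. All 5 major urinary protein genes measured fell as well: Mup5 by 5.67 ± 1.09, Mup4l4 by 4.65 ± 0.68, Mup4l1 by 4.15 ± 0.72, with Mup4l3 at least 9.35-fold and Mup4 at least 4.86-fold lower. Of the 3 isoflurane controls 1 was well above background for Ttr, Obp3, Mug1, Mug1l1, Rup2, Mup5 and Mup4l4 and 2 for Mup4l1. With signals raised to the background limit the differences were -5.07, -5.26, -3.87, -3.61, -4.24, -4.40, -4.65 and -3.99 in that order. Albumin differed by -5.33 ± 1.63 (adjusted p = 0.0639). Groups did not overlap in any of these 10 called genes. The calls of Ttr, Obp3, Mug1, Mug1l1 and Rup2 ended without CO2-O2 control 1 (0.101, 0.0680, 0.1, 0.0705 and 0.120) or 2 (0.113, 0.0747, 0.119, 0.0815 and 0.142), without isoflurane control 1 (0.102, 0.0652, 0.102, 0.0689 and 0.123) or 2 (0.111, 0.0666, 0.111, 0.0765 and 0.134), and with array row as a block (0.164, 0.113, 0.167, 0.116 and 0.197), where ranges began at 0.00926, 0.00323, 0.00794, 0.00565 and 0.00790. The call of Mup5 ended with array row as a block (0.0626, range from 0.00376). The call of Rup2 also ended without CO2-O2 control 3 (0.0532) and without CO2-O2 treated animal 1 (0.0572), 2 (0.0557) or 3 (0.0599). Of 40 further hepatocyte genes, listed after liver transcripts had been seen, 1 fell, 1 rose and 38 did not pass (median -0.19, camera, p = 0.0185, p = 0.242 with an estimated correlation). Of these 40, 31 were well above background in all isoflurane controls, such as Apom (6.63 and 6.61 in CO2-O2 and isoflurane controls). Added liver RNA could move such genes little, so the list as a whole cannot decide whether it was present.

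**Figure D4:**
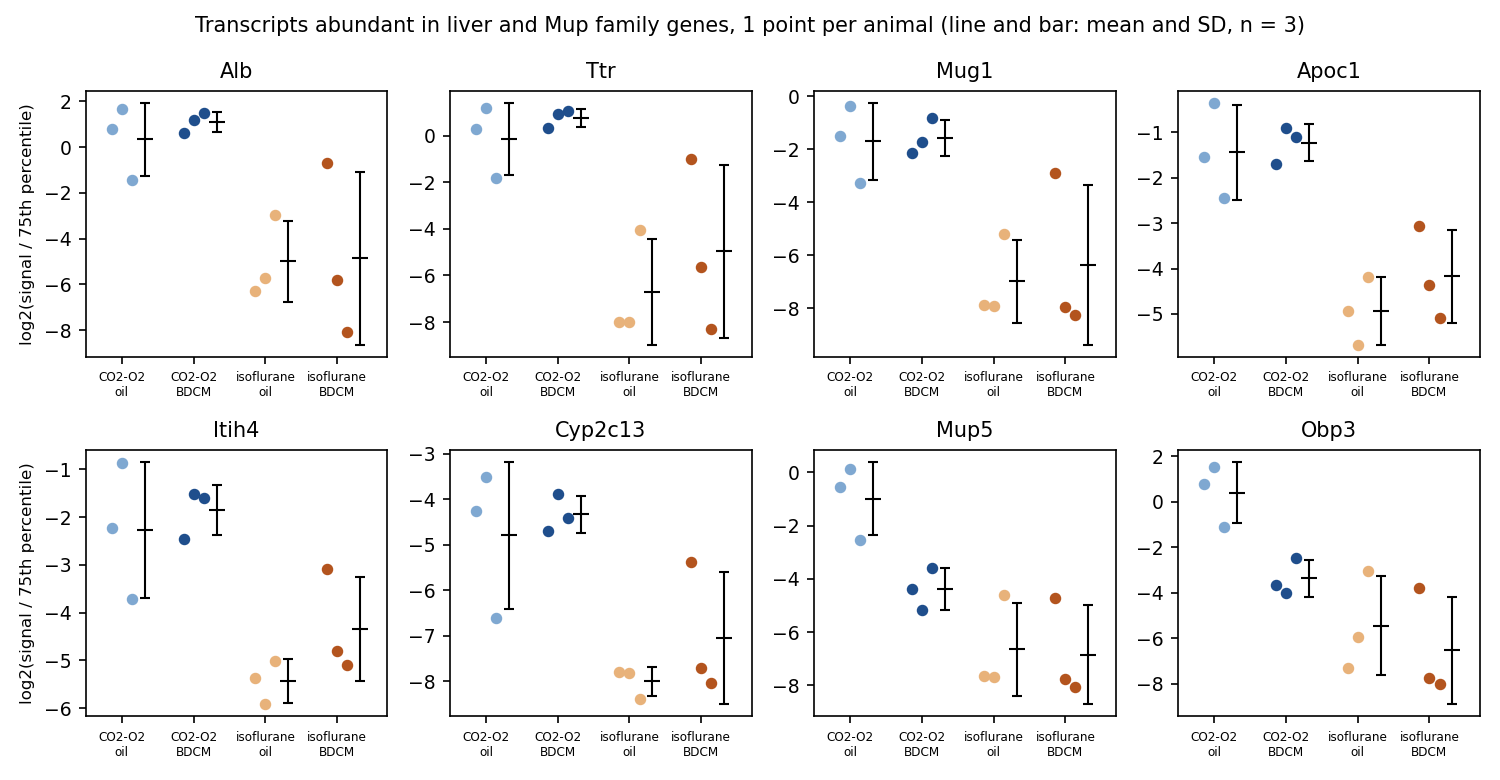
Normalized log2 signal of 8 transcripts abundant in liver in each of the 12 animals, with group mean and SD (n = 3). Alb lies between -1.44 and 1.66 in the CO2-O2 animals and between -8.07 and -0.69 in the isoflurane animals. For Alb, isoflurane control 3 and isoflurane treated animal 1 stand above the other animals of their groups. For Cyp2c13, isoflurane control 3 (-8.39) lies below isoflurane controls 1 and 2 (-7.81 and -7.84).

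Genes higher in the isoflurane controls included the splicing regulator Rbfox1 (5.09-fold, adjusted p = 0.00437), Msl3l2 (3.30-fold, adjusted p = 0.00151), the kallikrein-related peptidase Klk12 (3.27-fold, adjusted p = 0.00153) and the Wnt enhancer Rspo2 (4.26-fold, adjusted p = 0.0211). Several olfactory receptor genes were higher too: Or4k5 by 1.66 ± 0.26, Or2ag1 by 1.63 ± 0.26, Or51f4 by 1.69 ± 0.41, Or4x5 at least 2.56-fold and Or10d5jl at least 2.14-fold. For Adtrp, higher by 4.14 ± 1.14 (adjusted p = 0.0434), the other 2 probes differed by -0.36 and -0.11 and did not pass. The immediate early gene Fos was 2.71-fold higher (1.44 ± 0.24, adjusted p = 0.00649), the VEGF receptor Flt1 1.59-fold and the phosphate transporter Slc34a1 1.45-fold higher. Of the 3 CO2-O2 controls 1 was well above background for Rbfox1, Rspo2 and Or51f4, and with signals raised to the background limit these were 3.83-fold, 3.24-fold and 2.29-fold higher. For Klk12 and Or4k5 it was 2 of 3, and their differences did not move. In each of these genes all 3 isoflurane controls lay above all 3 CO2-O2 controls. The call ended for Rspo2 without CO2-O2 control 1 (0.0803; range 0.00927 to 0.116), for Or10d5jl without isoflurane control 2 (0.0576; 0.00756 to 0.0860), for Or51f4 without CO2-O2 control 1 (0.0642) or 2 (0.0767) or isoflurane control 1 (0.0655), 2 (0.0610) or 3 (0.0845; range 0.0130 to 0.102), for Flt1 (0.0963; 8.54e-04 to 0.0963) and Slc34a1 (0.211; 0.00125 to 0.211) with the mean of probes, and for Adtrp in 20 of 27 alternatives (7.08e-04 to 0.146), among them leaving out any 1 animal (0.0514 to 0.146) other than CO2-O2 control 3.

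Cell cycle genes were lower in the isoflurane controls by camera (adjusted p = 0.0158, median -0.27, adjusted p = 0.995 with an estimated correlation), though 1 of 38 members fell over all genes (Gins2, by 0.95 ± 0.23, adjusted p = 0.0275), 0 rose, and 0 passed when adjusted over the list alone. Cholesterol synthesis and uptake genes were lower too (adjusted p = 0.0493, median -0.14, adjusted p = 0.995 with an estimated correlation): 3 of 25 fell over all genes (6 fell and 1 rose when adjusted over the list alone), among them Cyp51 (by 0.46 ± 0.11, adjusted p = 0.0207). The call of Gins2 ended without CO2-O2 control 1 (0.0880) or 2 (0.0952) or isoflurane control 2 (0.0962) or 3 (0.0790), and that of Cyp51 without CO2-O2 control 1 (0.0756) or 2 (0.0649) or isoflurane control 1 (0.0531) or 2 (0.0777), within ranges of 0.00763 to 0.146 and 0.00348 to 0.0797. These 2 lists both lost their call under quantile normalization, median scaling and fry, and without CO2-O2 control 1 or 2 or isoflurane control 2 or 3. Their number was 1 without CO2-O2 treated animal 1 or 2 or isoflurane treated animal 1 or 3.

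By limma 3795 features differed between the controls, 2576 higher and 1219 lower with isoflurane (559 and 503 among named genes), and 13366 (39.1%) did not overlap, against 10% by chance. Higher calls made up 67.9%, but 54.3% under quantile normalization and 57.9% under median scaling. The count was 1630 without CO2-O2 control 1, 1758 without 2 and 2440 without 3, and 2219 without isoflurane control 1, 1860 without 2 and 2088 without 3. It was 2293 with array row as a block, 1776 without both isoflurane animals with high liver transcripts, and 6679 with array weights. Other probes of called genes shared the sign in 66.1% of cases (545 of 824), against 95.9% for the CO2-O2 BDCM effect. Anaesthesia, experiment, slide and scan day cannot be told apart here.

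The BDCM-treated groups of the 2 experiments were compared in the same way. Lower with isoflurane were some liver transcripts, among them Alb by 5.94 and Mug1l1 by 4.46 on the log2 scale (adjusted p = 0.0336 and 0.0276). Both calls ended without CO2-O2 treated animal 1 (0.0645 for Alb and 0.0510 for Mug1l1), 2 (0.0714 and 0.0535) or 3 (0.0872 and 0.0828) and without isoflurane treated animal 2 (0.0900 and 0.0825) or 3 (0.0869 and 0.0783), within ranges of 0.00688 to 0.152 and 0.00675 to 0.138. Ttr (-5.74), Rup2 (-5.40), Mug1 (-4.80) and Vstm2b (2.27) also passed (adjusted p = 0.0424, 0.0395, 0.0381 and 0.0463), but in only 9, 12, 13 and 9 of 26 alternatives, with ranges up to 0.194, 0.178, 0.177 and 0.142. The dimmer group was well above background on 1 of 3 arrays for Alb, Mug1l1, Rup2, Mug1 and Rbfox1 and on 2 for Ttr, Vstm2b and Sgpp2. With signals raised to the background limit the differences were -5.27, -3.01, -3.99, -3.34 and 1.85, and -4.99, 1.56 and 2.00. Higher with isoflurane were the interleukin-12 receptor chain Il12rb1 (at least 5.84-fold, adjusted p = 0.00144), Rbfox1 (2.31; adjusted p = 0.00377), Sgpp2, a sphingosine-1-phosphate phosphatase (2.26; adjusted p = 0.00240) and Or4x5 (at least 2.66-fold). Groups did not overlap in any of these genes. Of the 40 further hepatocyte genes 5 fell, 2 rose and 33 did not pass (median -0.34, camera, p = 2.08e-04, p = 0.0819 with an estimated correlation). By limma 5847 features differed, 4049 higher and 1798 lower, and 11473 (33.5%) did not overlap (10% by chance). Higher calls made up 69.3%, but 56.0% under quantile normalization. The count was 3635 without CO2-O2 treated animal 3, 3800 without isoflurane treated animal 1, 3247 with array row as a block and 973 when only these groups were fitted.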

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

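The tests chosen after the result was seen were those of Alb, Ttr and Mug1, of dim hepatocyte genes, of signal near background, of array position and the 3 of proximal tubule markers. The further hepatocyte list and its P450 genes were also chosen after liver transcripts had been seen.

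A difference between groups marked 8 gene lists, whose BDCM shift by camera was lower with isoflurane than with CO2-O2. They were extracellular matrix genes (adjusted p = 1.59e-05, median -0.24 with CO2-O2 and -0.62 with isoflurane), stromal and smooth muscle markers (4.19e-04, -0.19 and -0.40), mitochondrial respiratory chain genes (0.0365, -0.14 and -0.20), and, each at 0.0411, kidney injury markers (0.43 and 0.22), interferon-induced genes (0.19 and 0.14), proximal tubule markers (-0.60 and -0.64), podocyte and glomerular markers (-0.29 and -0.43) and endothelial markers (-0.15 and -0.30). With an estimated correlation the adjusted p was 0.820 for each. Extracellular matrix genes kept the call whichever animal was left out (highest 0.00427), as did stromal and smooth muscle markers (highest 0.0210), and the other 6 lists did not. For single genes the real count of differences was 0, so exchanges of animals between experiments test nothing here (100 of 100 give at least 0, the highest other 4).

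Liver transcripts such as Ttr and Mug1 were lower in isoflurane controls. The median difference of 40 further hepatocyte genes was -0.187 (95% bootstrap interval -0.341 to -0.014), which leaves hepatocyte RNA in the CO2-O2 samples open. It was -0.803 (-2.058 to -0.066) in the 6 of them with little kidney signal, against -0.220 in 634 other dim features. Acute-phase expression in the kidney stays open too, since its test rests on 2 measured P450 genes of the further hepatocyte list, Cyp2c7 (-2.92, adjusted p = 0.129) and Cyp8b1 (-0.83, adjusted p = 0.197), with a median of -1.874. For the fall of Mup genes with BDCM in the CO2-O2 experiment, less hepatocyte RNA in treated samples is argued against by Alb, Ttr and Mug1, whose median effect was 0.756.

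Between controls 3891 features were called among probes above background on all arrays and 2293 with array row as a block. This argues against signal near background, and against a row effect equal in all groups, as the whole cause. All CO2-O2 controls lay in row 1 and isoflurane controls 1 and 2 in row 2, so row and experiment are nearly confounded there. The column on the slide was not tested. With array row as a block 28 of 53 calls of named genes were kept, and for the others array position stays open. Other probes of called genes shared the sign in 66.14% of cases, so hybridization that differs by probe stays open for part of it. Anaesthesia, experiment, slide and scan day change together and cannot be told apart.

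Proximal tubule markers fell with BDCM (median -0.63). A smaller share of proximal tubule cells would raise markers of all other kidney cells alike, but the median of 9 other lists' medians was -0.173 (-0.389 to -0.132, all below 0). The highest median was -0.589 under another scaling and -0.533 without 1 animal (isoflurane treated animal 2), which argues against the choice among these scalings and against 1 animal as the cause. Each of the scalings brings the arrays to a common level, so an error that all of them share was not tested. RNA gained from cells in none of the lists was not tested, and lower expression per cell is left as a hypothesis.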

How the results depend on the processing

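No test here was chosen after the result was seen except the blocks by scan day, array row and value table number and leaving out both isoflurane animals with liver transcripts. Of 258 called results of named genes 152 kept the call in all alternatives, and 1 reversed (Fcgr2a). Of 68 called results of lists 0 did, since an estimated correlation ends each, and 1 reversed (proximal tubule markers). The cause was not tested, except that a stricter threshold lowers counts by construction. Signal over background limits what can be said of dim genes.

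Features called for the CO2-O2 BDCM effect (6810) numbered 3167 with slide and 4104 with scan day as a fixed block, 2850 at 0.01 and 1271 at 2-fold. For isoflurane (8923) they were 2715 with slide, 4222 at 0.01 and 2197 at 2-fold. For the mean (13037) they were 8329 with slide, 8117 at 0.01 and 1821 at 2-fold. For the difference of effects (0) they were 11 with slide and 20 with scan day. For controls (3795) they were 6679 with array weights, 2293 with array row, 1578 with the value table's number as block, 1776 without both liver-transcript animals, 1120 at 0.01 and 450 at 2-fold. For BDCM groups (5847) they were 3878 with no filter, 973 with only the groups compared, 3247 with array row, 2972 with the value table's number as block, 2968 without both liver-transcript animals, 1774 at 0.01 and 541 at 2-fold. The correlation of effects (0.766) was 0.844 with normexp, 0.594 with no filter, 0.838 above background on all 12 arrays, 0.660 with slide and 0.684 with scan day.

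Lists called for CO2-O2 (14) were 8 with slide, 9 with slide as a random block, 8 with scan day, 0 with an estimated correlation and 9 by fry. For isoflurane (17) and the mean (18) they were 0 with an estimated correlation. For the difference (8) they were 2 with normexp, 2 with no filter, 5 with the mean of probes, 13 with slide, 5 with the replicate block, 14 without both liver-transcript animals, 0 with an estimated correlation and 0 by fry. For controls (2) they were 0 with quantile or median scaling, above background on all 12 arrays, with the mean of probes, slide as a random block, without both liver-transcript animals, with an estimated correlation or by fry, 1 with normexp or the value table's number as block and 5 with no filter. For BDCM groups (9) they were 5 with normexp, 21 with no filter, 5 with slide as a random block, 0 with an estimated correlation and 0 by fry.

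With 1 animal left out, features ran from 3901 to 7743 for CO2-O2, 5446 to 9123 for isoflurane, 11189 to 13101 for the mean, 0 to 1 for the difference, 1630 to 4210 for controls and 3635 to 5236 for BDCM groups, the correlation from 0.728 to 0.765, and lists from 8 to 16, 15 to 21, 16 to 21, 2 to 15, 0 to 3 and 5 to 13.

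Reversed directions were those of Fcgr2a between controls (-0.003) and Cdkn1a for the mean effect (1.359), both with the mean of probes, and, for the difference of list shifts, of cell cycle genes without CO2-O2 treated animal 3 (0.00353), heat shock genes (0.0497) and red blood cell markers (0.0337) with slide as a block and proximal tubule markers without isoflurane treated animal 2 (0.940). Without 1 animal, the adjusted p of cell cycle genes ran from 3.56e-04 (lower with isoflurane, without CO2-O2 treated animal 1) to 0.63 (higher, without isoflurane control 1), and that of proximal tubule markers from 5.25e-05 (lower, without isoflurane treated animal 1) to 0.940.

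Same-numbered animals did not deviate together (r from -0.033 to 0.232, over 0.1 in 2 of 12 pairs), so the numbers do not pair the samples. With a replicate block, features were 4713, 6623, 11227, 0, 2632 and 4891, the correlation 0.766 and lists 15, 18, 19, 5, 3 and 11.

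Each contrast between 3 and 3 animals has 10 splits, too few for a share under 0.05. Of these, 1 gave as many features as the real one: 6810 (highest other 0), 8923 (1), 3795 (1) and 5847 (1). For the mean effect 1 of 100 splits gave 13037, the real one (highest other 2), which is the smallest share that 100 splits can give. This argues against chance. The other splits mix treated and control animals, so a strong BDCM effect widens their spread and lowers their counts. Splits cannot separate BDCM from slide or scan day, which differ in part between treated and control arrays.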

Other observations

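All gene families here were chosen after the data were seen. Members were taken by the pattern of their symbols. A family can therefore hold genes that are not subunits or factors of its kind, such as Psmc3ip among the proteasome genes.

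Cytosolic ribosomal protein and aminoacyl-tRNA synthetase genes rose with BDCM (mean of both experiments). Of 76 cytosolic ribosomal protein genes 73 rose and 0 fell (median 0.80, camera, adjusted p = 9.26e-42, adjusted p = 0.388 with an estimated correlation), among them Rps19 (1.25 ± 0.07). Their medians under other scalings ran from 0.591 to 0.836. Of 17 aminoacyl-tRNA synthetase genes 16 rose (median 0.70, adjusted p = 3.56e-08, 0.440 with an estimated correlation), among them Wars1 (1.54 ± 0.16) and Sars1 (1.20). Of 66 mitochondrial ribosomal protein genes 18 rose and 5 fell (median 0.06, adjusted p = 0.00692, 0.479 with an estimated correlation). Of 46 proteasome genes 22 rose (median 0.17, adjusted p = 4.80e-06, 0.440 with an estimated correlation), and of 47 initiation factor genes 22 rose and 2 fell (median 0.14, adjusted p = 5.13e-05, 0.440 with an estimated correlation), with Eif4ebp1, which encodes a repressor of initiation, up by 2.64 ± 0.23.

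Of 16 organic ion transporter genes of the Slc22 family 10 fell (median -0.72, adjusted p = 0.00229, 0.440 with an estimated correlation), among them Slc22a2 and Slc22a6 (-1.16). Between controls, 42 of 256 olfactory receptor genes were higher with isoflurane and 4 lower (median 0.29, adjusted p = 1.80e-04, 0.798 with an estimated correlation), with medians of 0.1 to 0.285 under the scalings. Between BDCM groups 50 were higher and 2 lower (median 0.32). Negative control probes had median signals of 5.89, 5.51 and 3.6 on the isoflurane control arrays and 3.48, 3.09 and 2.9 on the CO2-O2 control arrays. Whether this higher background accounts for the olfactory receptor difference was not tested.

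Of 5 major urinary protein genes 4 fell with BDCM in the CO2-O2 experiment and 1 in the isoflurane experiment. In the isoflurane experiment Mup4 and Mup4l3 were not well above background in either group, and Mup5 was well above it in only 1 of 3 animals of each, so a fall of these could not be seen there and the effects of the 2 experiments are not compared.

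The effect of BDCM in each treated animal was taken as a slope on the other experiment's effects, over the features called in that other experiment. It was 0.619, 0.834 and 0.790 with CO2-O2 (8909 features) and 0.795, 1.17 and 0.901 with isoflurane (6800 features). Choosing features by those calls can lower a slope, and the feature sets differ, so slopes are not compared between the experiments. The highest spike-in probe signal was 331.8 to 378.3 on CO2-O2 arrays and 787.1 to 1259 on isoflurane arrays, with 5 to 12 of 84 spike-in probes well above background.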
